A study of Brassica napus with 6 samples.

How the data were processed

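Shoot apices of normal and rod-like Brassica napus plants grown in the same field were sampled at early bolting, at 3 months, with 6 plants per RNA sample, per the labels. For the small RNA libraries, RNAs of 18 to 30 nt were cut from a gel from 10 µg of total RNA, ligated to adaptors, reverse transcribed, amplified by PCR and sequenced on an Illumina Genome Analyzer, per the labels' protocols. For the degradome libraries, polyadenylated RNA from about 200 µg of total RNA was ligated at 5′-monophosphate ends, cut with MmeI and amplified, per the labels' protocols. The mapper, annotation, target caller and thresholds are not given in the sources used here.

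The small RNA files hold whole-number counts per miRNA as deposited by the authors, separately for known and predicted miRNAs, with no normalization found in the values. Reads of near-identical family members could have been split or shared by the counting, which is not described. The degradome files hold, per the file headers, a score for each miRNA-target pair, with its cleavage position, category and P-value as the authors' target caller gave them. How the categories were defined is not stated, and lower categories were taken as stronger evidence, which is an assumption. Because tag counts are not part of the records used here, the planned ranking of pairs by tag abundance was not made. Names of predicted miRNAs in the degradome run up to 2242, beyond the 327 of the small RNA list, so these names were not joined between the data types. Target names were looked up in a RefSeq gene table, and 9 of 568 matched.

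The 2 files of each plant type were compared with a chi-square test, which found no more than counting noise, and were counted as 1 sample. Mean counts per file were scaled by edgeR's TMM factors to reads per 1000000 listed miRNA reads, and the ratio of rod-like to normal is given with an exact conditional 95% interval computed from the mean counts. PCR reads are not independent molecules, so intervals cover counting error only. Summed counts of 625795 to 713637 per file set the precision, and a miRNA near 100 counts is known far less well than miR168a with its mean of 190909 and 153318 counts.

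The test fixed before the data were examined was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr and robust fitting on the 4 files, with Benjamini-Hochberg adjustment at 0.05. As the files of a plant type may come from 1 pool, its p-values measure only the spread between these files. It was run on miRNAs and on counts summed by known family. Fixed lists numbered 7, set by family number, and lists with at least 3 tested members were tested with camera in limma 3.58.1. The standing of a list is the percentile of its median among 10000 random lists, each member drawn from the 20 miRNAs nearest in abundance. Correlations used 100000 permutations, two-sided. Tested on simulated data for the rod-like against normal comparison, with 200 miRNAs changed and a 2% spread, the edgeR step recovered 41.9% of 1.5-fold, 84.5% of 2-fold and 100% of 4-fold changes, with 4 false calls among 185 unchanged miRNAs. A simulation without change gave 0 calls among 372. Both drew the 4 files as independent replicates, so their false calls do not apply if the files of a plant type come from 1 pool. Simulations of that case are given further below.

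The miRNAs named are those of a rule fixed before the data were examined: up to 30 known miRNAs past the threshold by smallest adjusted p, 5 predicted miRNAs in each direction with files that do not overlap, the most abundant member of each list, the 5 most abundant miRNAs, every family past the threshold, and the best pairs of the degradome. A few others are named as list members to show the range, chosen after their values were seen: miR156h, miR171gf, miR171i, miR397ab, miR398b and miR6028. Alternatives covered the scaling, the low-count filter, DESeq2 1.42.0, limma on log2 CPM, thinning, a replicate block, each file left out, the list test, and the definition of a degradome pair. Tables were joined with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6.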

Results

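Small RNAs and cleaved transcript ends were sequenced from shoot apices of Brassica napus (oilseed rape) taken at the early bolting stage, when the plants were 3 months old. The study set normal plants against plants of a form called rod-like, which the labels do not describe further, and its title names the question: which miRNAs and targets are tied to plant architecture. Small RNA libraries were deposited as 2 files for normal and 2 files for rod-like plants, and degradome libraries, which capture the 5′ ends of cleaved transcripts, as 1 for each plant type. Each RNA sample came from 6 plants. The small RNA files list 74 known miRNAs, with names beginning bna, and 327 predicted miRNAs, which the authors named novel_mir_1 to novel_mir_327. Summed counts over the listed miRNAs were 625795 and 629101 in the normal files and 712169 and 713637 in the rod-like files. These sums cover listed miRNAs and are not the sequencing depth of the libraries.

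The 2 files of each plant type differed by no more than the sampling noise and were counted as 1 sample. A chi-square test over miRNAs with at least 10 summed counts gave a ratio of chi-square to degrees of freedom of 0.885 for the normal files (p = 0.952) and 1.05 for the rod-like files (p = 0.246). Between plant types the ratio was 116 to 118. Over miRNAs with a mean count of at least 100, the upper 95% limit of the variation between files beyond counting error was 0.783% in normal and 2.69% in rod-like plants. Counted in this way each plant type has n = 1, although the labels list 2 samples of each. The differences below were not checked against a spread between plant pools, and the tests compare these libraries, not the plant types. Folds are given with exact 95% intervals that cover counting error only, for mean counts per file scaled to reads per 1000000 listed miRNA reads (RPM).

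Between the libraries, miR408, miR2111, miR164, miR5654 and miR827 members stood higher in rod-like apices, and miR319 members stood lower. The abundance of miR408a, which targets copper proteins, was 8.96-fold higher in the rod-like sample (95% counting interval 7.12 to 11.4), from 125 to 1123 RPM. For miR319a, which targets TCP factors of leaf growth, abundance was 3.54-fold lower (2.89 to 4.35), from 650 to 184 RPM. Of the predicted miRNAs, novel_mir_1 went from 15722 to 75194 RPM, 4.78-fold higher (4.68 to 4.89). Of 391 miRNAs tested with edgeR's quasi-likelihood test, 110 passed a Benjamini-Hochberg adjusted p of 0.05, with 65 higher and 45 lower in the rod-like libraries. DESeq2's Wald test called 58, with 39 higher and 19 lower, and leaving out 1 file gave 71 to 87, with 48 higher and 23 lower without normal replicate 1. With scaling by the total count alone the split was 55 higher and 58 lower of 113. Among known miRNAs 34 were higher and 11 lower of 65 tested, and a fit scaled on the known miRNAs alone gave 22 higher and 23 lower, with fold changes 0.50 lower on the log2 scale at the median. Changes of at least 2-fold were found for 17 higher and 9 lower miRNAs.

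**Figure D1:**
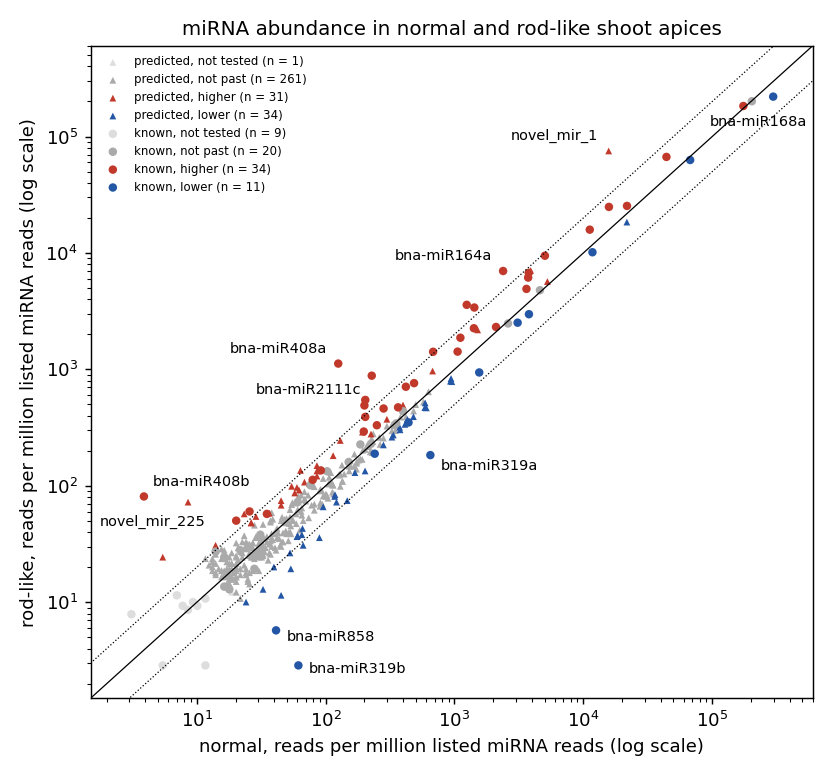
Abundance of each listed miRNA in normal (x axis) and rod-like (y axis) shoot apices, in RPM on log scales. Circles are known and triangles predicted miRNAs, colours give the outcome of the edgeR test between the libraries, the solid line marks equal abundance and the dotted lines 2-fold differences. The 2 miR408 members lie above and the 2 miR319 members below the dotted lines.

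The most abundant miRNA was miR168a, which targets AGO1. It took 30.4% of the listed counts in normal and 21.5% in rod-like files and was 1.35-fold lower (1.34 to 1.36) in the rod-like sample. By mean abundance over both plant types, the next were miR166e, miR158a, miR166f and miR172e. In the rod-like sample novel_mir_1 (75194 RPM) exceeded miR172e (66832 RPM), which exceeded miR166f (62894 RPM). For miR166e, which targets HD-ZIP III factors of organ polarity, the rod-like to normal ratio was 0.990 (0.983 to 0.997), and it did not pass the test. It did pass as lower with DESeq2's size factors, the total count alone, DESeq2's Wald test and scaling on known miRNAs alone. The ratio was 0.933 (0.920 to 0.945) for miR166f, which was lower, and 1.05 (1.04 to 1.06) for miR158a, which was higher in the test. Neither call held in a fit without a low-count filter, and miR158a lay at -0.43 on the log2 scale when scaled on known miRNAs alone.

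Members of the phase change list, miR156 and miR172, regulate SPL and AP2-type factors that time the passage from juvenile to adult growth and to flowering. Of 7 members tested, 6 were higher in the rod-like libraries, none was lower and 1, miR156h, did not pass. Adjusted over the list alone, the count was also 6. The abundance of miR172e was 1.51-fold higher (1.49 to 1.54), that of miR156bcg 1.57-fold higher (1.54 to 1.61) and that of miR156j 1.93-fold higher (1.56 to 2.39). The smallest called difference was that of miR156d-f, at 1.16-fold (1.14 to 1.19). With scaling on known miRNAs alone, miR156d-f and miR172d lay at -0.28 and -0.05 on the log2 scale. The list passed limma's camera test with a preset correlation (adjusted p = 0.0093) but not when the correlation was estimated, at 0.032 (adjusted p = 0.29). Lists with negative estimates, given below, lost their calls too. The loss therefore does not show correlation among the phase change members. Its median log2 fold change of 0.60 stood at percentile 77.2 of 10000 random lists matched on abundance, and at percentile 59.8 when these were drawn from known miRNAs.

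The organ polarity and meristem list moved in both directions. Of 10 members tested, 5 were higher, 3 lower and 2 not past the threshold; adjusted over the list alone, 6 were higher and 3 lower. The abundance of miR164a, which targets CUC boundary genes of the NAC group, was 2.94-fold higher (2.77 to 3.11), and that of miR164b-d 1.79-fold higher (1.71 to 1.88). In the miR171 family, which targets HAM genes of the GRAS group, miR171h was 1.69-fold (1.46 to 1.97) and miR171gf 1.33-fold (1.08 to 1.63) higher, and miR171i did not pass, with a ratio of 1.22 (0.955 to 1.56). Against these, miR319b went from a mean of 39.5 to 2 counts per file, a rod-like to normal ratio of 0.0467 (0.0055 to 0.180). The median log2 fold change of the list was 0.35 and its mean -0.19, so they differ in sign. The camera test, directed upwards, did not pass (adjusted p = 0.196). With scaling on known miRNAs alone the median was -0.15, and camera, then directed downwards, did not pass (adjusted p = 0.81). That scaling moved fold changes by -0.50 on the log2 scale at the median. The log2 fold change of miR171gf, 0.41, is smaller in size than this shift, so its direction depends on the scaling.

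For the auxin list, 3 of 8 tested members were higher, 2 lower and 3 not past the threshold, and the counts adjusted over the list alone were 3 and 2. The abundance of miR167a-c, which targets ARF6 and ARF8, was 1.41-fold higher (1.37 to 1.46). Its log2 fold change of 0.50 is about the size of the median shift of -0.50 under scaling on known miRNAs alone. Whether miR167a-c was higher therefore depends on the scaling. The abundance of miR390a-c, which triggers TAS3 small RNAs, was 1.16-fold lower (1.12 to 1.2), and that of miR160f was 1.23-fold lower (1.15 to 1.31). The list did not pass camera (adjusted p = 0.591). Its median of 0.10 on the log2 scale was -0.40 with scaling on known miRNAs alone.

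In the copper and lignin list only the 2 miR408 members passed of 4 tested, both higher, also when adjusted over the list alone. The fold of miR408b, 20.8 (6.2 to 129), rests on a mean of 2.5 counts in normal and 56.5 in rod-like files. For miR397ab, which targets laccases, the ratio was 1.22 (0.658 to 2.30), and for miR398b, which targets copper superoxide dismutases, 1.19 (0.771 to 1.86). Camera passed with the preset correlation (adjusted p = 0.016). With an estimated correlation, which was -0.016, the call was lost (adjusted p = 0.29). Positive correlation among the members therefore does not account for the loss. Without rod-like replicate 1 the adjusted p was 0.068.

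Of 18 tested members of the mineral nutrient list, 6 were higher, 3 lower and 9 not past the threshold; adjusted over the list alone, 7 were higher and 3 lower. The phosphate-responsive miR827 was 2.39-fold higher (2.21 to 2.58). The abundance of miR2111c was 3.87-fold (3.23 to 4.67) and that of miR2111abd 2.69-fold (2.20 to 3.31) higher. The 3 lower members were all of the miR169 family, which targets NF-YA factors, and miR169m was 1.65-fold lower (1.5 to 1.83). Camera did not pass (adjusted p = 0.196). With scaling on known miRNAs alone, miR2111e lay at -0.07 and the list median went from 0.22 to -0.27 on the log2 scale.

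The small RNA machinery list had 2 members, too few for a list test. The abundance of miR162b, which targets DCL1, was 1.57-fold higher (1.36 to 1.81), and that of miR168a was lower, as given above. In the list of Brassicaceae miRNAs and those related to PPR or NBS-LRR genes, 5 of 9 were higher, 1 was lower and 3 did not pass; adjusted over the list alone, 7 were higher and 1 lower. Among them miR158b was 1.88-fold (1.80 to 1.96), miR6030 2.08-fold (1.85 to 2.33) and miR1140 1.68-fold (1.54 to 1.85) higher, and miR6029 was 1.27-fold lower (1.2 to 1.35). Camera gave an adjusted p of 0.0488. With an estimated correlation, which was -0.061, the adjusted p became 0.29. Positive correlation among the members therefore does not account for the loss. The adjusted p was 0.0533 with DESeq2's size factors and 0.0614 with scaling by the total count, and lay between 0.0519 and 0.0706 when each of the 4 files was left out. In the fit on known miRNAs alone, which changed the scaling and the tested set together, none of the lists tested passed camera. The percentiles among random lists drawn from all and from known miRNAs were 99.8 and 98.85 for copper and lignin. They were 89.4 and 34.6 for organ polarity, 87.1 and 12.1 for mineral nutrients, and 74.15 and 35.2 for the Brassicaceae list. For small RNA machinery they were 38.15 and 23.5, and for auxin 29.3 and 7.35. The copper and lignin median of 1.72 on the log2 scale is that of 4 members. It lies between miR397ab (0.29) and miR398b (0.26) on one side and the miR408 members on the other. Random members were drawn singly, while list members can share a family, so a percentile can overstate how unusual a list is.

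**Figure D2:**
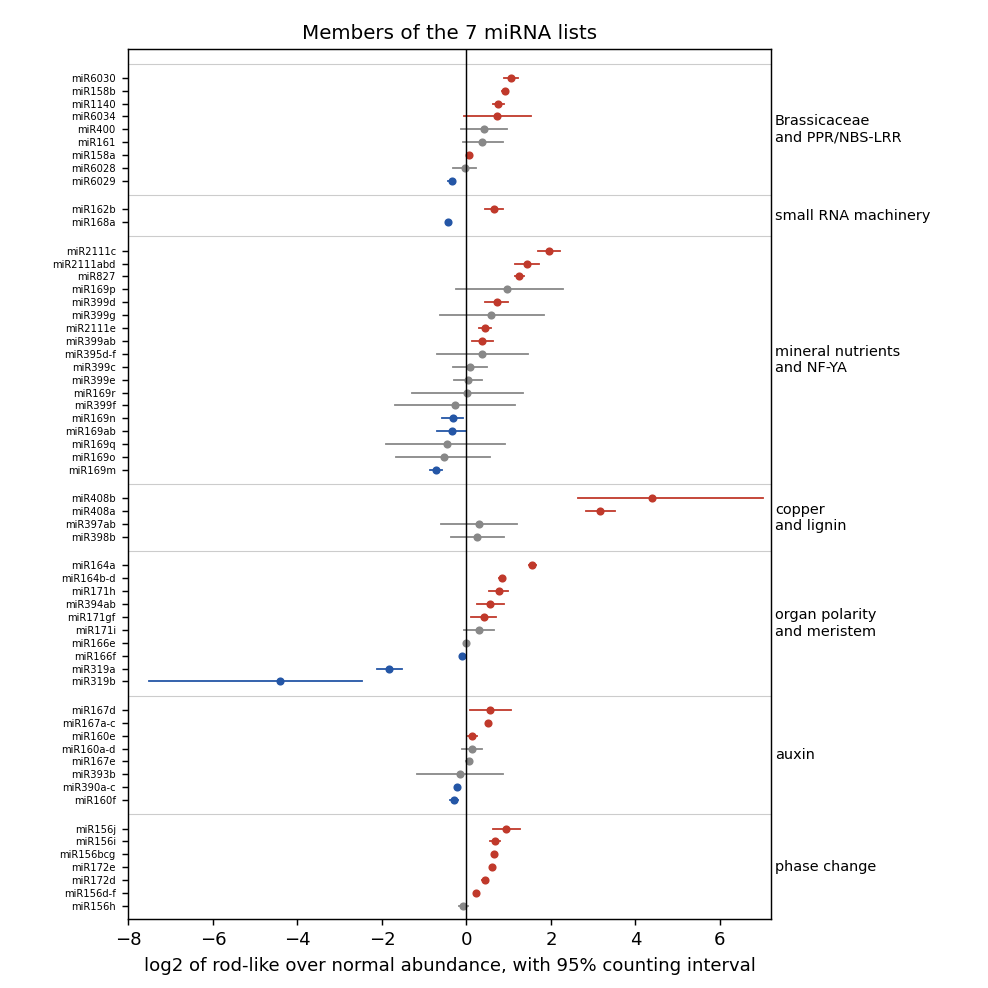
Log2 ratio of rod-like over normal abundance for each tested member of the 7 lists, with 95% counting intervals. Red points were higher and blue points lower in the edgeR test between the libraries, and grey points did not pass. The phase change members lie to the right of 0 apart from miR156h, while the organ polarity and meristem list holds both miR164 on the right and miR319 on the left.

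Outside the lists, miR5654 was 2.88-fold (2.66 to 3.13), miR9553 2.45-fold (2.0 to 3.03) and miR391 1.65-fold (1.57 to 1.73) higher. The other predicted miRNAs chosen by rank were mostly of smaller change. The abundance of novel_mir_3 was 1.81-fold (1.73 to 1.90), that of novel_mir_5 1.44-fold (1.33 to 1.57), that of novel_mir_8 1.43-fold (1.27 to 1.62) and that of novel_mir_225 8.47-fold (3.52 to 25.5) higher. In the other direction, novel_mir_209 was 3.93-fold (1.75 to 9.95), novel_mir_142 2.49-fold (1.53 to 4.16), novel_mir_81 1.97-fold (1.39 to 2.82), novel_mir_14 1.29-fold (1.11 to 1.5) and novel_mir_2 1.18-fold (1.15 to 1.21) lower. Predicted miRNAs took 8.20% and 8.25% of the listed counts in the normal files and 13.6% and 13.7% in the rod-like files. Without novel_mir_1 the shares were 6.59% and 6.65% in normal and 6.26% and 6.35% in rod-like files.

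Counts summed by family avoid the splitting of reads between near-identical members. Of 36 known families tested, 28 passed, 18 higher and 10 lower. The families miR408 (log2 fold change 2.97), miR5654 (1.28), miR9569 (1.06), miR9553 (1.04), miR827 (1.01), miR9409 (0.98), miR164 (0.91), miR6030 (0.81), miR2111 (0.69), miR1140 (0.50), miR391 (0.47), miR162 (0.40), miR172 (0.34), miR171 (0.32) and miR394 (0.32) were higher. So were miR156 (0.16), miR167 (0.14) and miR399 (0.12), but these 3 were negative with DESeq2's size factors. The families miR858 (-3.05), miR319 (-2.18), miR169 (-0.82), miR168 (-0.68), miR6029 (-0.59), miR390 (-0.46), miR160 (-0.33), miR6028 (-0.29) and miR166 (-0.28) were lower. Scaled as in the fit of single miRNAs, the median family lay 0.25 higher, and miR6028, a family of 1 member, did not pass in that fit, with a ratio of 0.973 (0.808 to 1.17). The miR158 family was lower as well (-0.15) but positive under scaling by the total count. The split depended on the scaling: it was 12 higher and 13 lower with DESeq2's size factors, which moved the median family by -0.26, and 22 higher and 8 lower with the total count, which moved it by 0.27.

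The degradome files give miRNA-target records with a cleavage position, an alignment score, a category from 0 to 3 and a P-value, without tag counts. The normal library listed 535 records of 138 miRNAs on 374 target transcripts, and the rod-like library 554 records of 148 miRNAs on 405 targets. Most of these miRNAs were predicted, 107 in the normal and 111 in the rod-like library, and 31 and 37 were of named families. Predicted miRNAs held 217 and 247 of the records, 5.99% and 10.1% of them in category 0. Of all listed miRNAs, 89 and 91 were 24 nt long. With 1 library per plant type, no test between plant types was made. Category 0 held 47.9% of records in the normal library (Clopper-Pearson 95% interval 43.5 to 52.2) and 54.2% in the rod-like library (49.9 to 58.4). These intervals, and those of shared pairs below, treat entries as independent. Yet the records covered only 416 target positions in each library, as several names can list the same site. All 41 records of the name ahy-miR156c, listed in the normal library alone, were in category 2. The targets are given by transcript identifiers, 9 of 568 of which matched the gene name table, and no gene names are given here.

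Among named families, miR156 had 51 targets in the normal and 31 in the rod-like library, and the 31 were shared. Without the name ahy-miR156c, listed in the normal library alone, there were 32 and 31. All 9 targets of miR164, 6 of miR160, 13 of miR5654, 4 of miR168 and 4 of miR394 were listed in both libraries. Targets numbered 17 and 20 for miR172, with 16 shared, and 12 and 11 for miR319, with 8 shared. The 13 targets of miR161 in the normal library compared with 5 in the rod-like library, all of them shared. Each library held 4 miR161 records in category 0. Families with targets in the rod-like library alone were miR398 with 4, miR390 and miR162 with 2 each, and miR397 and miR1140 with 1 each, and miR5716 had 1 target in the normal library alone. The miR398 targets were all listed under the name bol-miR398a-5p, in category 3. The best category was 1 for miR390 and miR1140 and 0 for miR162 and miR397. The miR397 record had a P-value of 0.048 from the target caller. In both libraries the best-scored pairs were 8 targets of bra-miR171e with a score of 0 and category 0, among them position 832 of BnaA03g21080D, and in the rod-like library a pair of novel_mir_49 with BnaCnng38740D was tied with them.

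**Figure D3:**
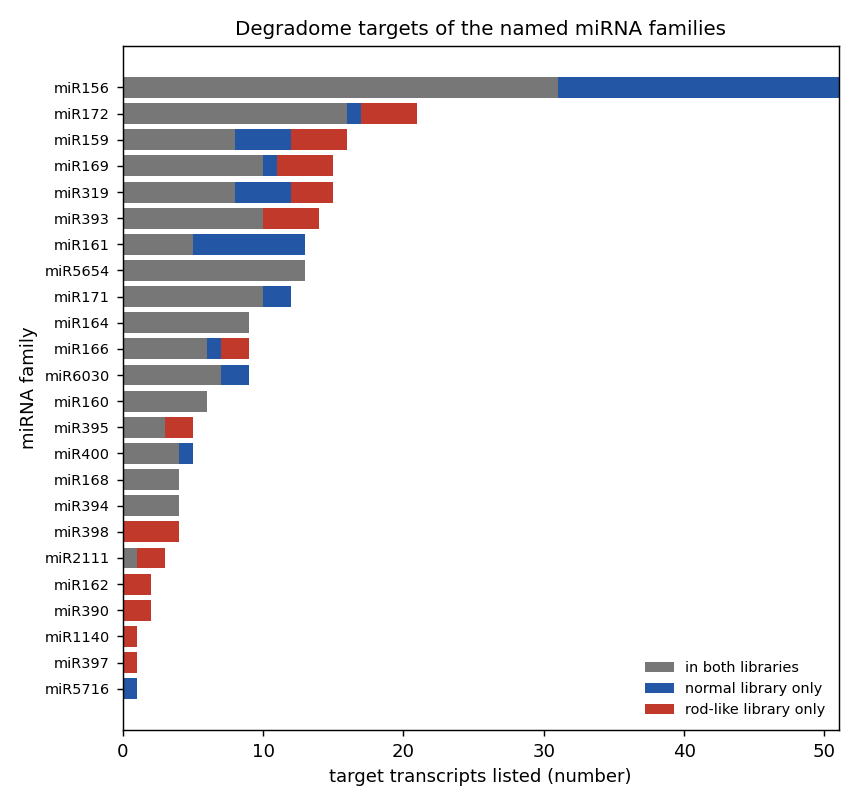
Number of target transcripts listed per named miRNA family in the degradome libraries of normal and rod-like apices. Grey bars count targets in both libraries, blue bars those in the normal library alone and red bars those in the rod-like library alone. The miR156 family has 31 shared targets and 20 listed in the normal library alone, which fall to 1 without the name ahy-miR156c.

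Of the miRNAs named above, those with targets under the same name were few. For miR166e the best score was 2.5 in category 0, shared by 4 pairs in the normal and 8 pairs in the rod-like library, with position 606 of BnaA08g11980D among them in both. For miR6030 it was position 599 of BnaCnng64090D in the normal library (score 0.5) and position 215 of BnaC08g15510D in the rod-like library (score 1, tied with another pair), in category 0. The best pair of miR2111c was position 268 of BnaA06g32400D in both libraries, with category 1 and score 2, and miR2111d had the same site in the normal library and position 220 of BnaA02g28650D, tied with another pair, in the rod-like library. In the rod-like library alone, miR1140 was paired with position 426 of BnaA01g02940D and miR169m with position 119 of BnaA01g20440D, tied with another pair, both in category 1. Also there alone, miR397a was paired with position 1204 of BnaA10g25170D in category 0.

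The libraries shared 309 of 762 pairs of miRNA and target, or 40.6% (37.0 to 44.1). With categories 0 and 1 alone the share was 60.9%. Those categories hold mostly named families, with 267 of 308 normal and 303 of 363 rod-like records. Pairs of family and target were shared to 66.0% (59.5 to 72.0) among named families, and pairs of predicted miRNAs to 17.7% (14 to 21.9). Of 313 records shared with their position, 268 had the same category.

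The labels number the rod-like degradome sample 3 and the rod-like small RNA samples 1 and 2, so the 2 kinds of data do not share a numbered rod-like sample. Across the 13 miRNAs found in both kinds of data, the change in abundance and the change in number of listed targets were not correlated beyond chance. Spearman's rho was -0.39 (permutation p = 0.183, adjusted p = 0.458) and Pearson's r was -0.31 (permutation p = 0.294, adjusted p = 0.735), over 5 relations computed. Without the 2 miRNAs farthest from the median fold change, rho was -0.16 and r was -0.10. This correlation is across miRNAs, which are not independent replicates.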

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

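The assumed spreads and the family fit on the miRNA-level scaling were chosen after seeing the data. The count of 110 miRNAs stayed within 1.5 times with DESeq2's size factors, total counts, no filter, a mean of at least 10, limma and thinning (99 to 113). It was 58 (39 higher, 19 lower) with DESeq2's Wald test, which gave no adjusted p for 69 miRNAs, 45 (22 and 23) with known miRNAs alone, where fewer were tested, and 26 (17 and 9) with a log2 fold change of at least 1. With the replicate block it was 53 (39 higher, 14 lower). The labels do not say what same-numbered files share beyond the number. Their deviations correlated at -0.087 over 109 miRNAs, but deviations that hold only counting noise cannot show or exclude a shared block. The block left the 28 families called and called 2 lists, with the Brassicaceae list at an adjusted p of 0.0558. Leaving out 1 file gave 71 to 87 miRNAs, with 23 to 34 lower; it was 71 without normal replicate 1, and the lower count was 23, 25 and 29 without normal replicate 1, normal replicate 2 and rod-like replicate 2. The lone file is then assumed to vary like the other plant type. With 1 summed library per plant type and an assumed spread between pools of 10%, 20% and 40%, 41 (31 higher, 10 lower), 12 (8 and 4) and 2 (1 and 1) miRNAs passed, and 16 (11 and 5), 4 (2 and 2) and 1 (1 and 0) families. The 12 at 20% were miR164a, miR2111abd, miR2111c, miR319a, miR319b, miR408a, miR408b, miR5654, miR858, novel_mir_1, novel_mir_209 and novel_mir_225. In simulations with no plant type difference and 1 pool behind both files, the edgeR test called a median of 41.5, 107.5 and 211.5 miRNAs at those spreads.

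Of 28 families called, 24 reversed in no alternative and, of 43 named miRNAs, 39. All 4 reversals of named miRNAs came from the fit on known miRNAs alone, in which predicted miRNAs could not reverse. With known miRNAs alone, 7 called miRNAs reversed in sign. Those named by the rule were miR172d (-0.054), miR156d-f (-0.28), miR2111e (-0.068) and miR158a (-0.43 on the log2 scale). Named outside the rule, miR171gf stood at 0.41 in the fit of all miRNAs. The median shift of -0.50 under that scaling takes miR171gf below 0 as well. The median of the Brassicaceae list reversed as well (-0.088). So did those of the organ polarity and meristem (-0.15), mineral nutrient (-0.27), auxin (-0.40) and small RNA machinery (-0.39) lists, which had no camera call. The phase change (0.10) and copper and lignin (1.23) medians stayed positive, the latter lying between the miR408 members and the others tested. That scaling lowers every known miRNA. With DESeq2's size factors and its Wald test, the families miR156 (-0.10 in both), miR167 (-0.12 in both) and miR399 (-0.14 in both) reversed. The miR158 family reversed to 0.12 with total counts and 0.10 with the miRNA-level scaling. DESeq2's Wald test called 22 families, 10 higher and 12 lower. Of the 6 lists tested, 3 passed camera; 0 passed with an estimated correlation (0 at an unadjusted p under 0.05), 0 with known miRNAs alone (1 unadjusted), and 2 each with DESeq2's size factors and total counts, where the Brassicaceae list was lost. For the 3 lists that passed, the estimated correlations were 0.032 (phase change), -0.016 (copper and lignin) and -0.061 (Brassicaceae). The negative ones cannot account for those losses, and the loss of the phase change call does not show correlation among its members. The fry test, which asks whether a list moves on balance one way and does not compare it with other miRNAs, passed 5. Leaving out 1 file gave 1 to 2 lists, with 1 without rod-like replicate 1. The family fit uses known miRNAs already, so that alternative changes nothing there. Categories 0 and 1 alone left 308 normal and 363 rod-like degradome records, by construction fewer. The share of common pairs was 36.2% by family and target and 60.9% in categories 0 and 1. The correlation with target numbers passed no threshold in any alternative. Apart from smaller sets by construction, the cause was not tested. At the simulated depth 41.9% of 1.5-fold changes were recovered; depth was not varied there, and thinning to the shallowest file gave 99 calls.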

Other observations

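The tests of miRNAs listed in 1 library and of degradome categories were chosen after the results were seen; those of known against predicted miRNAs were chosen before. Among miRNAs outside the naming rule, chosen after its values were seen, miR858, which targets MYB factors of flavonoid synthesis, went from a mean of 26.5 to 4 counts per file and was 7.18-fold lower (2.5 to 28.3) in the rod-like sample. In the degradome, ahy-miR156c had 41 targets in the normal library and none in the rod-like library. On 22 of these a further miR156 site was listed, and in 22 of 22 the ahy-miR156c position lay 1 nt further 3′. The remaining 19 had no other miR156 site from the 2 names compared. The listed ahy-miR156c sequence (21 nt) has 1 nt more at its 5′ end than those 2 names (20 nt). A position counted from that end shifts by 1 nt by construction, so the offset does not show separate cleavage sites. All 41 records were in category 2, with a P-value of 0.004 from the target caller. Of 146 groups of 2 or more records with the same miRNA, category and library, 126 had a single P-value throughout.

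Known miRNAs stood higher than predicted miRNAs in the rod-like libraries, with median log2 fold changes of 0.41 and -0.04. Low counts of the predicted miRNAs are argued against as the cause, since among miRNAs with a mean count of at least 100 the excess was 0.53 (bootstrap 95% interval 0.17 to 0.78). A single large family is argued against as well: the lowest excess on leaving out 1 family, miR2111, was 0.41 (0.17 to 0.62). Both intervals treat miRNAs as independent, although members of a family can share reads, so they can be too narrow. Scaling moves both classes alike and cannot bear on the excess. A difference between plant types, and one between 2 pools of plants, may both account for it and stay untested.

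Of 762 degradome pairs, 453 were listed in 1 library only. The listing of whole miRNAs may account for part of this: among miRNAs with at least 2 pairs, 53.0% of single-library pairs belonged to a miRNA with no pair in the other library, against 4.84% to 12.5% in 95% of shuffles of library membership. Weaker evidence, if lower categories are stronger, is a further candidate explanation: category 0 was 54.8 percentage points rarer among records of single-library pairs (19.5%) than among shared ones (74.3%). This gap was not separated from the class of miRNA. Category 0 held 76.4% (normal) and 89.6% (rod-like) of records of named families, and 5.99% and 10.1% of those of predicted miRNAs. Pairs of miRNA and target were shared to 63.2% among named families and to 17.7% among predicted miRNAs. The plant types have 1 degradome library each, so a biological difference stays untested.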
